A study of Homo sapiens with 6 samples.

How the data were processed

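RNA of MM1S cells was measured on 6 arrays, 3 of normoxia and 3 of hypoxia for 24 h; the group of each array came from its condition label, and the replicate numbers 0 to 2 from its title. The treatment text, which names 24 h of hypoxia, was the same on all 6 arrays, those labelled normoxia included, so it did not set the groups, and how the normoxia cells were handled is not given in the sources used here. Per the labels' protocols, total RNA was isolated with the RNeasy kit, converted to cDNA and amplified by in vitro transcription into biotin-labelled cRNA. The deposited table holds 1 linear intensity per probe set and array, for 54613 probe sets. How the authors corrected the background, summarised the probes and scaled the arrays is not given in the sources used here. The sorted intensities of the arrays differed by up to 1260.1, so the probe set values themselves were not forced to one distribution, while normalization of probes before their summary is not excluded. In each array 2.44% to 2.58% of the values were exactly 1, and 2 to 7 values lay below it, so 1 is not a strict floor. No detection calls were used here, so a low intensity cannot be told from background, and the number of arrays limits the precision. All 15 pairs of arrays were compared before averaging: 1.07% to 1.23% of their values were identical, less than the share at 1 in each array, so each array was counted as 1 sample. The replicate numbers were not taken as pairing the arrays of the conditions, a decision resting on correlations of deviations over all genes, chosen after those over brighter genes had also been seen; not every array correlated best with its own number. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.991 to 0.995 within and 0.969 to 0.974 between groups.

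Probe sets were named through the platform annotation supplied with the table. Of the probe sets, 41091 carried 1 gene symbol, 1801 several and 11721 none here, and the last 2 kinds were left out. Entrez identifiers of 41037 of the single-symbol probe sets were found in a RefSeq gene table, through which symbols were brought up to date; no genome build is named for the arrays, so no coordinates are given. Each gene was represented by the single-symbol probe set with the highest mean log2 value over all 6 arrays, with no filter on dim genes, which gave 19775 genes, 10523 of them with several probe sets. Of 4388 such genes past the threshold, 391 (8.91%) had another probe set past it in the opposite direction; among the genes named by rule these were CR2, HK2, MKI67 and TFRC. Array control probe sets, and with them RNA degradation and hybridisation controls, are not analysed here.

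Intensities were turned into log2(intensity + 16). Hypoxia was compared with normoxia with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with no covariates and Benjamini-Hochberg adjustment over all genes tested; the threshold was an adjusted p of 0.05, and confidence intervals are at the 95% level. A set of 29 gene lists was tested with camera of limma, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Of these, 10 passed, 3 upward and 7 downward, and 6 passed with the correlation estimated for each list: HIF targets, hydroxylases and demethylases, MYC and ribosome biogenesis, replication, homologous recombination and mismatch repair, and the integrated stress response. The median, the mean and the direction of the test differed in sign for the lists of the HIF pathway, the tricarboxylic acid cycle, apoptosis, interferon, mature B cells, and erythroid and epithelial markers. None of them passed in camera. Leaving out both arrays numbered 0, leaving out genes above a log2 intensity of 13 and removing HIF targets from other lists were chosen after seeing the data. So were the further lists of the closing part. The design, the 29 lists, the other alternatives and the rule for named genes were fixed before the data were examined. By that rule, the text names the 10 genes with the largest rise and the 10 with the largest fall in log2(intensity + 16) among those past the threshold whose groups did not overlap, up to 4 members of each list with the smallest adjusted p, and 13 genes set in advance (HIF1A, EPAS1, LDHA, HK2, VEGFA, CA9, CXCR4, MYC, IRF4, MAF, CCND2, SDC1 and CD38). List members outside the rule are said to be named after their values were seen, and the 6 brightest glycolytic genes were listed by their brightness. Lists overlap in few genes, the most being 5 between the HIF targets and the hydroxylases and demethylases.

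The procedure was tested on simulated data with the spread of these arrays, in which 50 genes were changed at each of 4 sizes among 19775 genes: 2 were recovered at a log2 change of 0.3, 30 at 0.5, 38 at 1 and 49 at 2, with 5 false calls among 124. The changed genes were drawn only from those above a set normoxia intensity, so the recovery of dim genes was not tested. Far fewer genes were changed than were called in the real data, so these shares do not carry over to it. A simulated shifted list passed in camera, and 0 of 20 random lists did. The simulated noise was independent between genes, so camera was not tested on lists whose members vary together. Among the real lists the estimated correlation was 0.195 for glycolysis and 0.173 for the proteasome. Alternatives were the replicate number as a block, each array left out in turn, quantile normalization, median centring, filters on dim genes at the 25th percentile and the median of brightness, the mean of a gene's probe sets, probe sets without those marked as binding several transcripts, an intensity trend or robust fit in eBayes, array weights, pseudocounts of 1 and 64, a 2-fold minimum, unmoderated statistics, probe sets in place of genes, an estimated correlation, and the fry test, which asks only whether the members of a list move, on balance, one way. The mean of a gene's probe sets weighs dim and bright ones equally, so a probe set without signal draws it towards 0. Probe sets marked as binding several transcripts were those with the suffix _x_at. Figures were drawn with matplotlib 3.10.9.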

Results

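Gene expression was profiled on 6 single-colour oligonucleotide arrays in MM1S, an established human cell line of multiple myeloma, a cancer of plasma cells. RNA came from cells kept in normoxia on 3 arrays and from cells held in hypoxia for 24 h on 3 arrays, to find the transcripts whose levels differ between the conditions. The oxygen concentration was not given in the sources used here. Each array gave an intensity for 54613 probe sets, with an array median of 54.95 to 60.1, and 19775 genes were read by 1 probe set each. Levels are given below as the mean ± SD of the intensity (n = 3 arrays per group), and changes as hypoxia minus normoxia on the log2(intensity + 16) scale, which understates the change of dim genes. Arrays of the same group lay closer to each other than arrays of different groups. The SD of the log2 difference between paired arrays over all genes was 0.25 to 0.33 within a group and 0.57 to 0.62 between groups. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

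Many genes differed between the conditions, in both directions. In limma with Benjamini-Hochberg adjustment, 3335 genes (16.9%) rose and 4068 (20.6%) fell past an adjusted p of 0.05, while 12372 did not pass. At least 2-fold changes were seen in 577 of the genes that rose and 940 of those that fell. The 3 arrays of one condition all lay above the 3 of the other for 9471 genes (47.9%), against 10% by chance.

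On the log2(intensity + 16) scale the largest rise was that of SCNN1G, the gamma subunit of the epithelial sodium channel, which went from 135 ± 8.41 to 4425 ± 131 (log2 change 4.88, 95% confidence interval 4.72 to 5.04, limma adjusted p = 1.36e-05). It was followed by MIR210HG, the host transcript of a hypoxia-responsive microRNA, at 4.28, by the long non-coding RNA DIRC3 at 4.18, and by PFKFB4, an enzyme that sets the level of an activator of phosphofructokinase, at 4.05. PPFIA4 rose by 3.77, the lipid droplet protein gene HILPDA by 3.58, the cyclin-dependent kinase inhibitor CDKN1C by 3.28 and the histone gene H2AC6 by 3.22. EFEMP2, an extracellular matrix protein of elastic fibres, and EPHA1-AS1, annotated as an antisense transcript, rose by 3.09 and 2.92. The largest fall on that scale was that of UHRF1, which helps to maintain DNA methylation through replication, from 3794 ± 97.2 to 337 ± 15.8 (log2 change -3.43, 95% confidence interval -3.58 to -3.28, limma adjusted p = 1.90e-05). Replication genes made up part of the other large falls, with GINS3 at -2.84, POLE2 at -2.75 and MCM10 at -2.70. FAM111B fell by 2.95, the spliceosomal isomerase PPIL1 by 2.92, PIGW, an enzyme of glycosylphosphatidylinositol anchor synthesis, by 2.87, and CHAC2, a glutathione-degrading enzyme, by 2.87. The splicing regulator ESRP1 and the phosphatase DUSP2 fell by 2.69 and 2.65. Adjusted p-values of these 20 genes in limma were at most 6.77e-05. In normoxia DIRC3 (11.5 ± 3.51), PPFIA4 (47.9 ± 8.62), H2AC6 (50.1 ± 8.87), EFEMP2 (25.8 ± 7.08) and EPHA1-AS1 (43.8 ± 6.50) lay below the median probe set of every array, as did ESRP1 in hypoxia (24.5 ± 4.72). At such levels signal cannot be told from background, so the sizes of these changes and their order are uncertain. Averaged over all probe sets of a gene, the changes of SCNN1G, PFKFB4 and EPHA1-AS1 were 2.59, 2.28 and 1.36. The other probe set of SCNN1G was at 6.33 in normoxia and 11.4 in hypoxia, where signal cannot be told from background. It did not pass, so the rise given for SCNN1G rests on 1 of its 2 probe sets. The order depends on the scale: with a pseudocount of 1 the largest changes were those of DIRC3 (5.31, SCNN1G 5.03) and AMOTL2 (-4.17). With the mean of a gene's probe sets the largest rise was that of DIRC3.

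**Figure D1:**
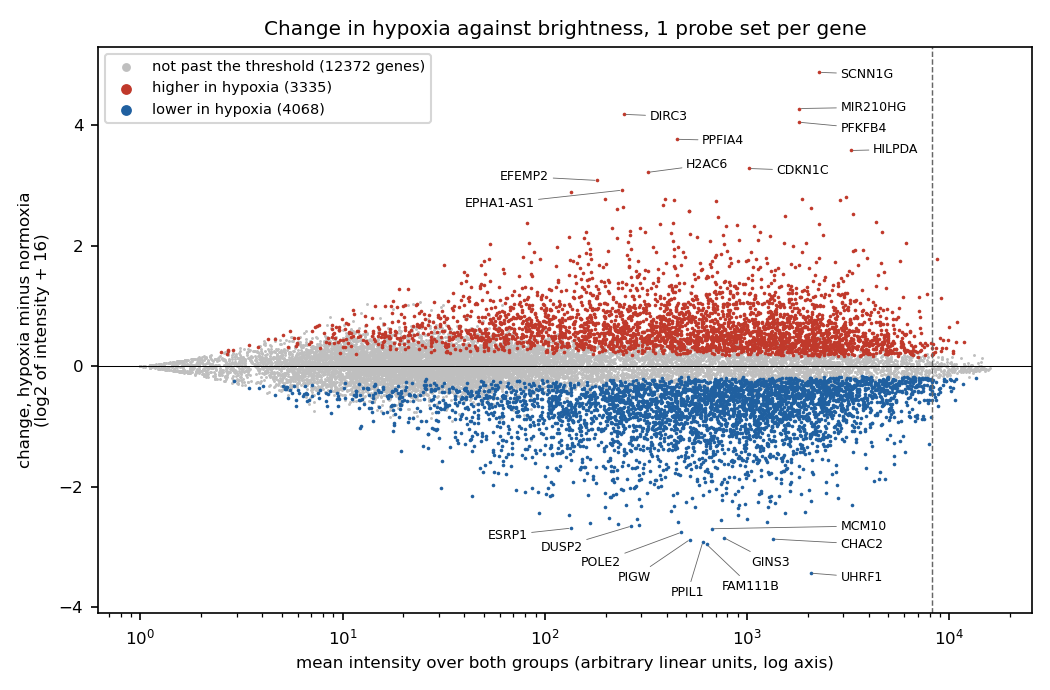
Change of each of 19775 genes (vertical axis, hypoxia minus normoxia, log2 of intensity + 16) against its mean intensity over both groups (horizontal log axis, arbitrary linear units). Red points are the 3335 genes that rose, blue points the 4068 that fell and grey points the 12372 that did not pass; the dashed line marks a log2 intensity of 13, to the right of which few points lie far from 0.

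Targets of the hypoxia-inducible factors (HIF), the transcription factors that are stabilised at low oxygen, rose as a group. Of 34 measured targets, 26 rose and 8 did not pass (26 and 0 adjusted over the list alone), with a median change of 1.24 (camera adjusted p = 7.32e-15). HILPDA went from 492 ± 47.2 to 6052 ± 69.7, the lipoprotein receptor gene VLDLR from 88.9 ± 3.19 to 700.0 ± 41.7, the collagen prolyl hydroxylase gene P4HA1 from 1376 ± 69.8 to 7263 ± 148 and NDRG1 from 1612 ± 67.7 to 7643 ± 319. The vascular growth factor gene VEGFA rose by 0.70, from 2715 ± 94.9 to 4413 ± 208 (limma adjusted p = 0.000412). The 8 targets that did not pass, named after their values were seen, were BNIP3, MIF, LOX, CA12, CITED2, ANGPTL4, STC2 and EGLN3, with mean intensities in hypoxia of 5.87, 11954, 40.9, 72.9, 426, 47.4, 25.2 and 33.0. Of these, MIF (at 10887 ± 821 in normoxia and 11954 ± 519 in hypoxia) and CITED2 (at 386 ± 87.2 in normoxia and 426 ± 135 in hypoxia) were not dim. CA9 was not analysed here, since no probe set carried its symbol alone. The call of the list held with an estimated correlation (adjusted p = 0.0243).

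Genes of glucose uptake and glycolysis rose together as well, but by very different amounts. Of 20 measured members, 16 rose and 4 did not pass (17 and 0 adjusted over the list alone), with a median change of 0.65 (camera adjusted p = 1.28e-08, lost at adjusted p = 0.164 with an estimated correlation). The regulatory enzyme genes PFKFB4 and PFKFB3 went from 193 ± 17.9 to 3434 ± 20.9 and from 404 ± 13.3 to 1396 ± 34.9, the aldolase gene ALDOC from 729 ± 19.6 to 5048 ± 202 and the glucose transporter gene SLC2A3 from 565 ± 48.4 to 3557 ± 54.1. The hexokinase gene HK2 rose by 1.06, from 2709.8 ± 75.01 to 5677 ± 137. LDHA, which encodes a subunit of lactate dehydrogenase, was at 11664 ± 281 in normoxia and 12002 ± 249 in hypoxia (log2 change 0.041, 95% confidence interval -0.092 to 0.17, limma adjusted p = 0.624). The other members that did not pass, named after their values were seen, were GAPDH at -0.032, PFKP at 0.16 and PKM at 1.23, the last with a hypoxia SD of 425 around a mean of 747. Another probe set of PKM rose from 170 ± 17.7 to 807 ± 94.3 (log2 change 2.14, limma adjusted p over all probe sets = 9.99e-05). The 6 members with a log2 intensity above 13 (TPI1, GAPDH, PGK1, PGAM1, ENO1 and LDHA) had a median change of 0.28, and the other 14 one of 1.14. Changes were small in that range over all genes: the 95th percentile of the absolute log2 change was 0.46 over the 205 genes above 13 and 1.32 over the 3496 genes between 10 and 12. For HK2 the mean of its 3 probe sets fell by 0.41 (limma adjusted p = 0.00210), as both dimmer probe sets fell.

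**Figure D2:**
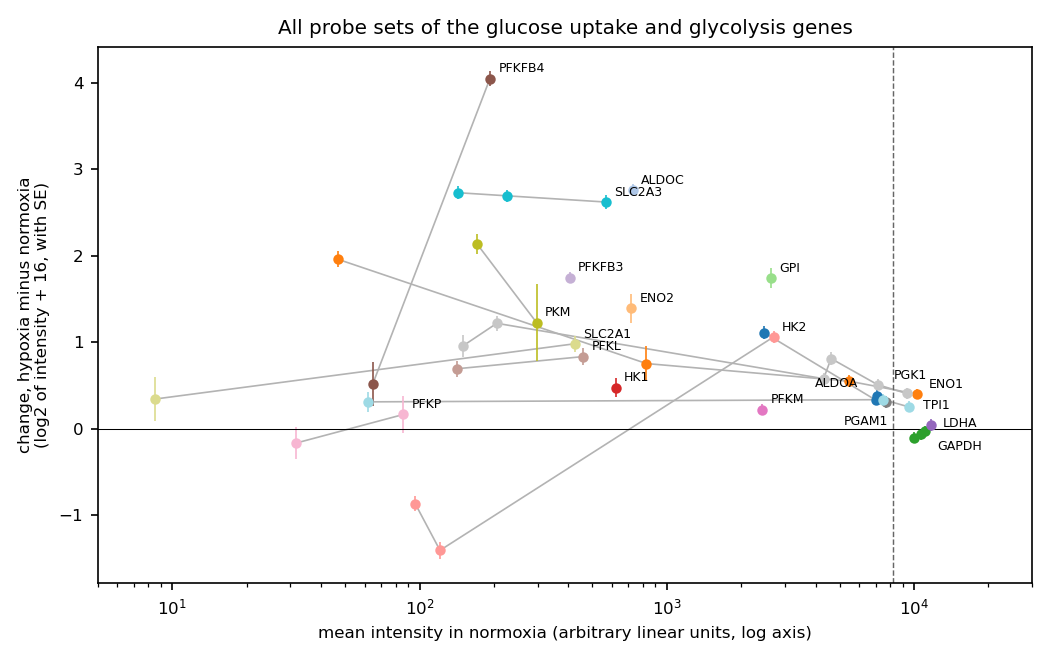
Change of every probe set of the 20 glucose uptake and glycolysis genes (vertical axis, hypoxia minus normoxia, log2 of intensity + 16, with SE bars) against its mean intensity in normoxia (horizontal log axis, arbitrary linear units); grey lines join probe sets of the same gene, the label stands at the brightest in normoxia, and the dashed line marks a log2 intensity of 13. From brightest to dimmest the probe sets of ENO1 read 0.40, 0.55, 0.75 and 1.96, the last at 46.6 in normoxia, where signal cannot be told from background, while the dimmer probe sets of HK2 read -1.41 and -0.87.

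The transcripts of the oxygen-sensing pathway itself moved in both directions. HIF1A, the alpha subunit that oxygen destabilises as a protein, was at 2814 ± 58.9 in normoxia and 2813 ± 8.45 in hypoxia (log2 change -0.00013, 95% confidence interval -0.13 to 0.13), and EPAS1, its paralogue, was at a log2 change of 0.18 (limma adjusted p = 0.0691; 0.0409 and 0.0173 when dim genes were left out). Of 16 pathway members, 4 rose, 2 fell and 10 did not pass (4 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.578). The oxygen sensor gene EGLN1 rose by 1.27, the HIF partner gene ARNT by 0.63 and the coactivator gene CREBBP by 0.46, while ELOC, part of the ubiquitin ligase that removes HIF, fell by 0.44. The 2 others that passed, named after their values were seen, were EP300 at 0.55 and VHL at -0.66. The call of CREBBP was lost with the mean of its probe sets (0.24, limma adjusted p = 0.0608).

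Genes of oxygen-dependent hydroxylases and demethylases, enzymes that use molecular oxygen as a substrate, rose as a group. The list also holds P4HB, a subunit of collagen prolyl hydroxylase that does not itself use oxygen. Of 27 members, 18 rose, 2 fell and 7 did not pass (18 and 2 adjusted over the list alone), with a median change of 0.59 (camera adjusted p = 1.16e-07; adjusted p = 0.0402 with an estimated correlation). The prolyl hydroxylase genes P4HA1 and P4HA2 rose by 2.39 and 2.15, and the histone demethylase genes KDM3A and KDM4B by 2.05 and 1.89. The members that fell, named after their values were seen, were ASPH at -0.34 and FTO at -0.34. The list shares 5 members with the HIF targets, and without them its median change was 0.41 (camera adjusted p = 0.000117). The median of the list was 0.26 with the mean of a gene's probe sets, where P4HA1 and P4HA2 rose by 1.25 and 0.88.

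**Figure D3:**
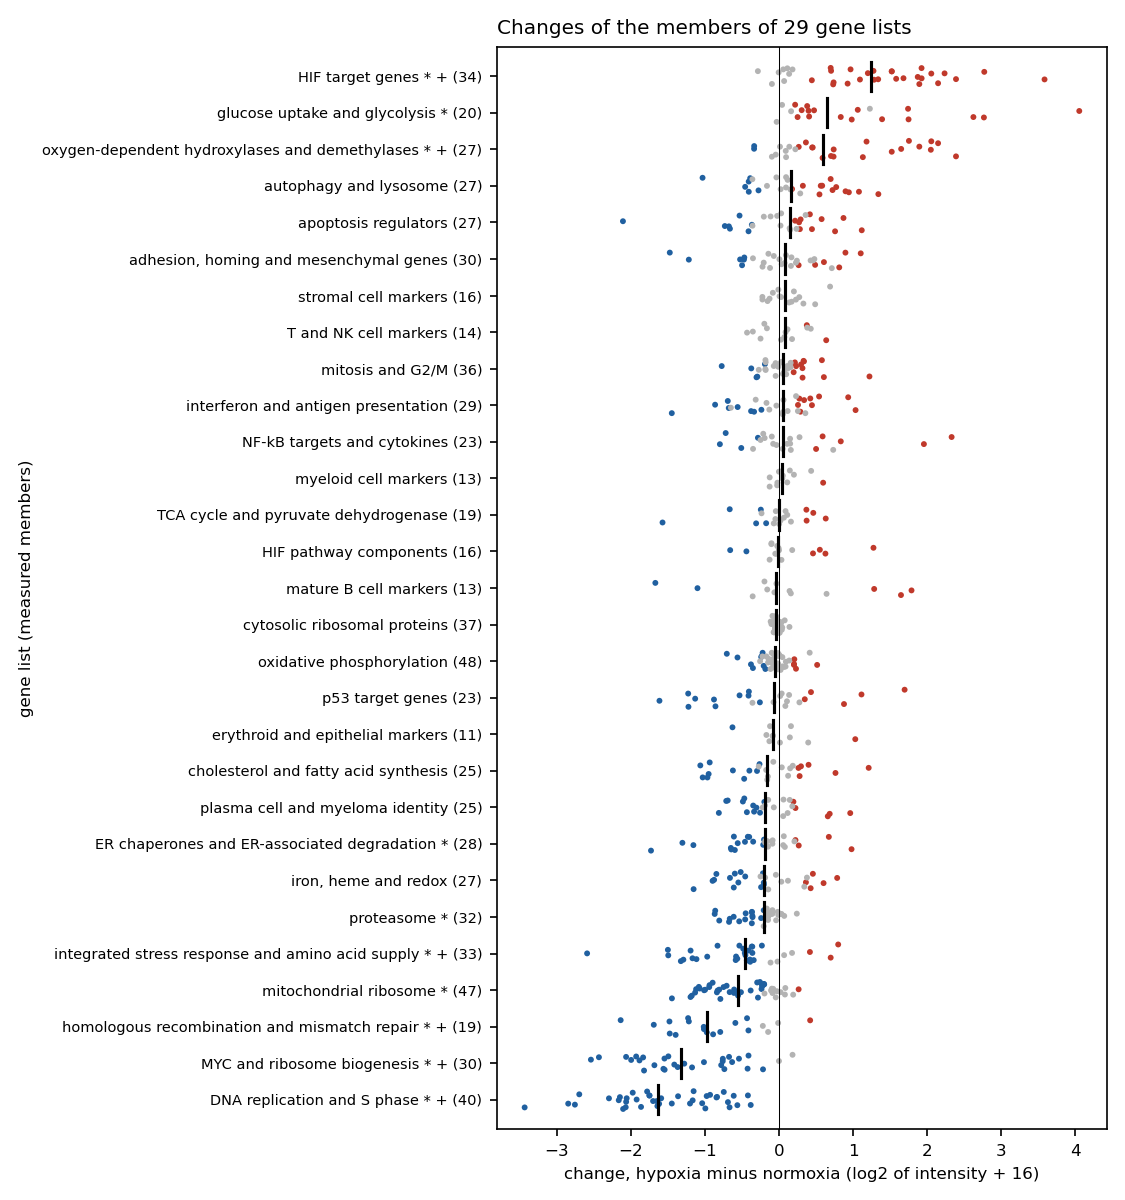
Changes of the measured members of the 29 gene lists (horizontal axis, hypoxia minus normoxia, log2 of intensity + 16), 1 row per list with its number of measured members, ordered by the median (black bar). Red and blue points are members that rose or fell past the adjusted p threshold in limma and grey points are members that did not pass; an asterisk marks the 10 lists past the threshold in camera and a plus sign the 6 that also passed with an estimated correlation.

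Mitochondrial genes were split between those of the mitochondrial ribosome, which fell, and those of respiration, whose lists did not pass in camera. Of 47 mitochondrial ribosomal protein genes, 35 fell, 1 rose (MRPS5, named after its value was seen, at 0.26) and 11 did not pass (2 and 35 adjusted over the list alone), with a median change of -0.55 (camera adjusted p = 4.31e-09, lost at adjusted p = 0.167 with an estimated correlation). MRPS17 fell from 2548 ± 109.7 to 926 ± 44.8, MRPL16 from 2879 ± 48.8 to 1352 ± 20.7, MRPS23 from 3473 ± 113 to 1576 ± 34.8 and MRPS7 from 1326 ± 43.4 to 623 ± 41.0. Among 48 genes of oxidative phosphorylation, 5 rose, 9 fell and 34 did not pass (5 and 8 adjusted over the list alone; median -0.053, camera adjusted p = 0.427). In fry this list and that of the tricarboxylic acid cycle passed downward (fry adjusted p = 0.0428 and 0.0182). The median normoxia intensity was 7078 for oxidative phosphorylation and 2709 for the mitochondrial ribosome, and changes of brighter genes were smaller, so these lists are not compared at like brightness. ATP5MC1 and ATP5PF, subunits of ATP synthase, fell by 0.70 and 0.38, the cytochrome c gene CYCS fell by 0.56 and UQCRC2, a subunit of complex III, rose by 0.51. The tricarboxylic acid cycle and pyruvate dehydrogenase genes numbered 19, of which 4 rose, 5 fell and 10 did not pass (4 and 5 adjusted over the list alone; median 0.0020, mean -0.057, camera adjusted p = 0.943). DLAT, a subunit of pyruvate dehydrogenase, fell from 2239 ± 47.2 to 744 ± 68.0, and IDH3A fell by 0.67, while IDH3G and SUCLG2 rose by 0.63 and 0.46. The call of IDH3G was lost with the mean of its probe sets (0.18, limma adjusted p = 0.502), and those of CYCS and SUCLG2 were kept at -1.20 and 0.30. The other probe set of IDH3G was dim, at 17.9 in normoxia and 10.6 in hypoxia.

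MYC and genes of ribosome biogenesis fell nearly throughout, and genes of the ribosomal proteins did not pass. MYC, a transcription factor that drives growth genes, went from 7539.6 ± 225 to 3098 ± 83.4 (log2 change -1.28, 95% confidence interval -1.42 to -1.14, limma adjusted p = 4.56e-05). With MYC, 28 of 30 members fell and 2 did not pass (0 and 28 adjusted over the list alone), with a median change of -1.32 (camera adjusted p = 1.74e-14; adjusted p = 0.0241 with an estimated correlation). NOP16 fell from 2617 ± 113 to 473 ± 27.0, MRTO4 from 1705 ± 24.8 to 451 ± 19.2, URB2 from 454 ± 21.3 to 102 ± 6.56 and the pseudouridine synthase gene PUS7 from 1363 ± 66.7 to 371 ± 18.9. The members that did not pass, named after their values were seen, were NOB1 at 0.18 and NPM1 at -0.00055. Of 37 cytosolic ribosomal protein genes, 0 passed in limma, 0 passed when adjusted over the list alone and 0 at an unadjusted p of 0.05, with a median change of -0.042 (camera adjusted p = 0.518; fry adjusted p = 0.0623). RPL6, RPL10A, RPS10 and RPL8, the members with the smallest adjusted p, were at -0.11, -0.10, -0.085 and -0.089, and the first 3 passed when limma was given an intensity trend (adjusted p = 0.0127, 0.0139 and 0.0330). The median normoxia intensity of this list was 12876, in the range above a log2 intensity of 13 where changes were small over all genes. NOP16 fell by 1.13 when averaged over its probe sets, and RPL6 passed with median centring (limma adjusted p = 0.0418). The brighter probe sets of NOP16 were at -2.43 and -2.74, and the others, at 67.6 and 62.5 in normoxia, did not pass.

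Genes of DNA replication fell without exception among those measured, while the list of mitosis genes did not pass in camera. All 40 measured replication and S phase genes fell (0 and 40 adjusted over the list alone), with a median change of -1.63 (camera adjusted p = 2.12e-23; adjusted p = 0.0361 with an estimated correlation). UHRF1 fell as given above, the polymerase epsilon subunit gene POLE2 from 836 ± 28.3 to 111 ± 9.69, the replication initiation gene MCM10 from 1178 ± 52.4 to 168 ± 11.1 and the flap endonuclease gene FEN1 from 5490.3 ± 129.7 to 1106 ± 20.8. Of 36 mitosis genes, 12 rose, 5 fell and 19 did not pass (12 and 8 adjusted over the list alone), with a median change of 0.060 (-0.0051 with median centring; camera adjusted p = 0.264). In fry the mitosis list passed upward (fry adjusted p = 0.000597). The proliferation marker gene MKI67 rose from 1876 ± 93.8 to 4391 ± 136, and the kinase genes BUB1 and NEK2 by 0.61 and 0.58, while the cyclin gene CCNB1 fell by 0.37. The others that fell, named after their values were seen, were KIF11 at -0.77, KIF23 at -0.30, BUB1B at -0.29 and CCNA2 at -0.19. Per array, the mean log2 value of the replication genes minus that of the mitosis genes was -0.19 ± 0.0124 in normoxia and -1.81 ± 0.0532 in hypoxia (exact two-sided permutation test with the arrays unpaired, p = 0.1, the smallest that 3 against 3 arrays allow). With same-numbered arrays taken as pairs, the differences were -1.67 to -1.57 (exact sign flips, p = 0.250, the smallest for 3 pairs). Both tests were chosen after the values were seen, and whether the numbers pair the arrays is not settled. Homologous recombination and mismatch repair genes also fell, with 15 of 19 lower, 1 higher (XRCC2, named after its value was seen, at 0.42) and 3 not past the threshold (1 and 15 adjusted over the list alone; median -0.97, camera adjusted p = 3.32e-07, adjusted p = 0.0318 with an estimated correlation). The helicase genes BRIP1 and BLM fell by 1.69 and 1.22, and PALB2 and RMI1 by 1.48 and 1.23. The probe sets of MKI67 disagreed: 2 rose (1.22 and 1.12) and 2 fell (-1.09 and -0.60), with a mean of 0.16 (limma adjusted p = 0.125).

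**Figure D4:**
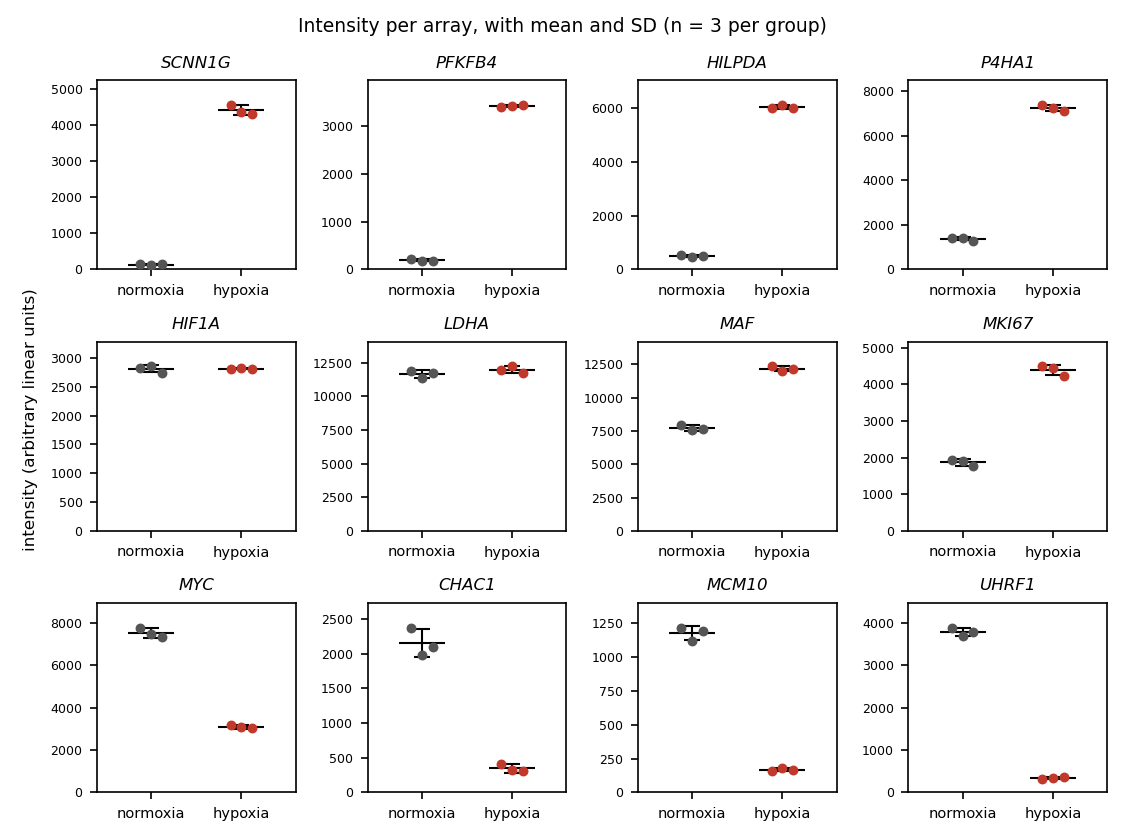
Intensity of 12 genes on each array (vertical axes, arbitrary linear units, starting at 0), with grey points for the 3 normoxia and red points for the 3 hypoxia arrays, and black bars for the mean and SD. The values of the conditions are fully apart for SCNN1G (135 ± 8.41 to 4425 ± 131) and UHRF1 (3794 ± 97.2 to 337 ± 15.8), and lie at the same level for HIF1A (2814 ± 58.9 in normoxia and 2813 ± 8.45 in hypoxia).

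Genes of the integrated stress response and of amino acid supply fell. Of 33 members, 26 fell, 3 rose and 4 did not pass (3 and 26 adjusted over the list alone), with a median change of -0.45 (camera adjusted p = 1.41e-07; adjusted p = 0.0306 with an estimated correlation). The folate enzyme gene ALDH1L2 fell from 2233 ± 35.7 to 779.6 ± 25.3, the tryptophanyl-tRNA synthetase gene WARS1 from 1821 ± 62.2 to 718 ± 33.2, the serine synthesis gene PSAT1 from 11225 ± 269.5 to 4583 ± 256.2 and the glutathione-degrading enzyme gene CHAC1 from 2152 ± 201 to 346 ± 59.5. The members that rose were VEGFA and, named after their values were seen, NUPR1 at 0.80 and PPP1R15A at 0.42. Of 28 chaperone and degradation genes of the endoplasmic reticulum, 14 fell, 4 rose and 10 did not pass (5 and 14 adjusted over the list alone; median -0.20, camera adjusted p = 0.0245, lost at adjusted p = 0.324 with an estimated correlation). MANF and CRELD2 fell by 1.16 and 1.30 and DERL2 by 0.65, while ATF6, a sensor of unfolded proteins, rose by 0.67. The other members that rose, named after their values were seen, were the sensor gene ERN1 at 0.98, XBP1 at 0.22 and P4HB at 0.27. Proteasome genes fell as well, with 16 of 32 lower and 16 not past the threshold (0 and 17 adjusted over the list alone; median -0.21, camera adjusted p = 0.000118, lost at adjusted p = 0.389 with an estimated correlation). PSMC3 fell by 0.86, PSMA5 by 0.67, PSMD1 by 0.87 and PSMD12 by 0.66. The call of the endoplasmic reticulum list was also lost with quantile normalization (camera adjusted p = 0.0757) and without dim genes (0.0674 and 0.159). Its median moved to -0.43 with the mean of a gene's probe sets, where PSMA5 and PSMD12 were at -1.26 and -1.09 and ATF6 at 0.42, and to -0.35 without genes above a log2 intensity of 13.

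Lipid synthesis, redox and autophagy genes changed in both directions, and none of these lists passed in the reported camera test. Of 25 cholesterol and fatty acid synthesis genes, 6 rose and 10 fell (8 and 10 adjusted over the list alone; median -0.16, camera adjusted p = 0.488). The sterol carrier gene STARD4 rose by 1.21, while ACACA, which commits carbon to fatty acid synthesis, PMVK of the mevalonate pathway and ACAT2 fell by 0.95, 0.97 and 1.03. Of 27 iron, heme and redox genes, 5 rose and 14 fell (7 and 14 adjusted over the list alone; median -0.21, camera adjusted p = 0.130). The thioredoxin reductase gene TXNRD1 fell from 6542 ± 96.7 to 3508 ± 44.5, SRXN1 from 1478 ± 83.6 to 656 ± 36.3, the transferrin receptor gene TFRC from 9538 ± 184 to 5194 ± 266 and GCLM, of glutathione synthesis, from 571 ± 30.2 to 310.4 ± 4.77. Those that rose, named after their values were seen, were TKT at 0.78, SLC11A2 at 0.60, CAT at 0.46, ALAS1 at 0.43 and HMOX1 at 0.36. Of 27 autophagy and lysosome genes, 12 rose and 6 fell (12 and 6 adjusted over the list alone; median 0.16, camera adjusted p = 0.0515). GABARAPL1 rose by 1.34, the lysosomal protease gene CTSB by 0.94, ATG2A by 0.77 and ATG14 by 0.90. Several alternatives put this list past the threshold. Among them were normoxia replicate 0 or normoxia replicate 2 left out (camera adjusted p = 0.0404 and 0.0420), quantile normalization (0.0307) and fry (fry adjusted p = 0.000687, upward). In fry the lipid synthesis and redox lists passed downward (fry adjusted p = 0.00862 and 0.000640). Averaged over their probe sets, TFRC lost its call (-0.23, limma adjusted p = 0.0727) and TXNRD1 was at -0.32.

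Genes of plasma cell and myeloma identity moved both ways. Of 25 members, 5 rose, 11 fell and 9 did not pass (5 and 11 adjusted over the list alone; median -0.19, camera adjusted p = 0.456). The receptor genes TNFRSF13B and CD28 rose from 1449 ± 35.9 to 2839 ± 168 and from 4030.1 ± 135 to 6482 ± 99.3, and the transcription factor gene MAF from 7717 ± 216 to 12186 ± 183. The surface marker genes CD38 and SDC1 fell by 0.71 and 0.30, and IRF4, a transcription factor on which myeloma cells depend, was at 5886 ± 361 in normoxia and 6116 ± 223 in hypoxia (95% confidence interval -0.12 to 0.23). The others that rose, named after their values were seen, were XBP1 at 0.22 and POU2AF1 at 0.19. The cyclin gene CCND2 fell by 0.20 (limma adjusted p = 0.0348), a call lost when any 1 of the 6 arrays was left out (adjusted p = 0.0519 to 0.107) and under quantile normalization (0.102). Its dimmer probe sets were at -0.56, -0.87 and -0.81 (limma adjusted p over all probe sets = 0.00424, 0.0271 and 0.0149). The mean of its probe sets also passed (limma adjusted p = 0.000901). Markers of mature B cells, from which plasma cells arise, also moved both ways, with 3 of 13 higher and 2 lower (3 and 2 adjusted over the list alone, median -0.034, camera adjusted p = 0.602). Their list passed upward in fry (fry adjusted p = 0.00309). BCL6 and PAX5, transcription factors of B cells, rose from 33.7 ± 0.827 to 157 ± 23.1 and from 85.8 ± 2.37 to 303 ± 21.05, as did EBF1, named after its value was seen, by 1.28, while the B cell surface genes MS4A1 and CR2 fell by 1.67 and 1.10. SDC1 and CCND2 were at -0.52 and -0.61 when averaged over their probe sets, and BCL6 and PAX5 at 0.82 and 0.80. That average lost the call of CR2 (-0.12, limma adjusted p = 0.553), whose other probe set was at 6.12 in normoxia and 24.8 in hypoxia. With a pseudocount of 64 BCL6 was at 1.17.

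Among 30 adhesion, homing and mesenchymal genes, 6 rose and 6 fell (9 and 6 adjusted over the list alone; median 0.084, camera adjusted p = 0.578). The intermediate filament gene VIM rose from 2043 ± 4.47 to 4408 ± 189, the transcription factor gene ZEB1 by 0.90 and the selectin ligand gene SELPLG by 0.61. The cadherin gene CDH2 fell from 167 ± 7.74 to 50.03 ± 2.63, and CXCR4, the chemokine receptor that holds plasma cells in the bone marrow, fell by 0.47, from 2229.7 ± 137 to 1604 ± 137 (limma adjusted p = 0.00757). Of 23 NF-kB targets and cytokines, 5 rose and 4 fell (6 and 4 adjusted over the list alone; median 0.049, camera adjusted p = 0.578). The cytokine gene IL10 rose from 251 ± 11.9 to 1323 ± 47.5, TRAF1 by 1.95 and TNFSF13B by 0.59, while PLEK fell by 0.72. The others that passed, named after their values were seen, were RELB at 0.83 and TNFAIP3 at 0.50 among those that rose, and CCL4 at -0.80, NFKBIA at -0.51 and CD83 at -0.28 among those that fell. Of 29 interferon and antigen presentation genes, 9 rose and 8 fell (9 and 10 adjusted over the list alone; median 0.055, mean -0.029, camera adjusted p = 0.651). The transcription factor genes IRF7 and IRF9 rose by 1.03 and 0.93 and IFI6 by 0.54, while OAS2 fell by 0.69. Averaged over their probe sets, CDH2, VIM and TRAF1 were at -0.95, 0.66 and 0.88.

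Apoptosis regulators and p53 targets also went both ways. Of 27 apoptosis regulators, 10 rose and 7 fell (10 and 9 adjusted over the list alone; median 0.14, mean -0.00047, camera adjusted p = 0.629). PMAIP1, which promotes apoptosis, fell from 4017 ± 165 to 923 ± 91.7, and the genes BID and FADD fell by 0.68 and 0.66, while APAF1, a part of the apoptosome, rose by 1.12. Of 23 p53 targets, 5 rose and 10 fell (5 and 11 adjusted over the list alone, median -0.074, camera adjusted p = 0.488). The p53 list passed downward in fry (fry adjusted p = 0.00257). TP53INP1 rose from 773 ± 24.9 to 2540.4 ± 122, while TIGAR, TRIAP1 and AEN fell by 1.61, 1.23 and 1.22. The others that rose, named after their values were seen, were ZMAT3 at 1.11, SESN1 at 0.88, CCNG1 at 0.43 and DDB2 at 0.35. BID and TP53INP1 were at -1.41 and 0.59 when averaged over their probe sets.

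Most stromal, myeloid, T and NK cell, erythroid and epithelial markers were dim, the brightest being HBB, CD247 and SPARC, and none of their lists passed. Of 16 stromal markers, with a median normoxia intensity of 52.2, 0 passed in limma, 0 passed when adjusted over the list alone and 0 at an unadjusted p of 0.05 (camera adjusted p = 0.602; fry adjusted p = 0.453). SPARC (intensity 478 ± 33.8 in normoxia and 563 ± 55.3 in hypoxia), COL1A1, DCN and KDR were at log2 changes of 0.23, -0.22, 0.17 and 0.27. None of these 4 passed, but KDR did without both arrays numbered 0 (limma adjusted p = 0.0414), as did SPARC and COL1A1 over genes above the median brightness (0.0431 and 0.0497). Of 13 myeloid markers, with a median of 28.1, 1 rose in limma (0 and 0 adjusted over the list alone, 1 and 0 at an unadjusted p of 0.05; fry adjusted p = 0.424, camera adjusted p = 0.602), namely CD163 from 14.03 ± 5.37 to 29.3 ± 8.06. ITGAM, LYZ and CSF3R were at 0.15, -0.13 and -0.13. Of 14 T and NK cell markers, with a median of 45.3, 2 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.578), namely CD247 from 1073 ± 98.9 to 1677 ± 156 and CD3D by 0.38. CD2 and NKG7 were at -0.43 and 0.43. Of 11 erythroid and epithelial markers, with a median of 32.8, 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.943), namely EPCAM from 24.8 ± 4.04 to 67.3 ± 9.97 and HBB from 1751 ± 128 to 1125 ± 27.7. CLDN4 and ALAS2 were at 0.39 and -0.086. The calls of CD163 and CD3D were lost without normoxia replicate 0 (limma adjusted p = 0.112 and 0.107), normoxia replicate 2 (0.108 and 0.111), hypoxia replicate 0 (0.0506 and 0.0756), hypoxia replicate 1 (0.0856 and 0.112) or hypoxia replicate 2 (0.106 and 0.0729). CLDN4 passed without hypoxia replicate 1 (limma adjusted p = 0.0208). The calls of CD163 and CD3D were also lost with median centring (limma adjusted p = 0.0584 and 0.0802). With the replicate number as a block CD163 lost its call too (limma adjusted p = 0.0505). The call of CD3D was lost with quantile normalization (limma adjusted p = 0.0886) and an intensity trend (0.0506). That of CD163 was lost with a pseudocount of 1 (limma adjusted p = 0.0637), with the mean of its probe sets (0.274, at 0.12) and without probe sets that can bind several transcripts, where it was at -0.30. HBB was at -0.031 without such probe sets (limma adjusted p = 0.812), CD247 at 0.29 when averaged over its probe sets (0.182) and EPCAM at 0.56 with a pseudocount of 64. SPARC and COL1A1 passed without the dimmer genes (limma adjusted p = 0.0431 and 0.0497).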

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

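The fit over all probe sets was planned, and its counts by kind of annotation were chosen after the result was seen. Probe sets outside the gene comparison also differed between the conditions. Among the 11721 probe sets with no gene symbol here, 1881 were higher and 792 lower in hypoxia past an adjusted p of 0.05 in limma, fitted over all probe sets. Among the 1801 probe sets with several symbols, 308 were higher and 323 lower. They were listed because they carry a difference that the comparison of named genes leaves out, and no explanation of it was tested.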

How the results depend on the processing

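Of the alternatives, leaving out both arrays numbered 0, leaving out genes above a log2 intensity of 13 and removing HIF targets from the other lists were chosen after seeing the data. The counts of genes higher in hypoxia and genes lower in hypoxia were 577 and 940 with a 2-fold minimum, and 8481 and 8289 over probe sets in place of genes. The count of gene lists past the threshold was 6 with an estimated correlation and 20 with fry. When each array was left out in turn, 2771 to 3291 genes were higher, 3432 to 3932 lower and 10 to 11 lists passed. Under the other alternatives all 3 counts stayed within 1.5 times the reported ones. Median centring gave 2865 higher and 4697 lower genes, 37.9% of them higher against 45.0%, and leaving out both arrays numbered 0 gave 3199 and 3720. Of the 7403 genes called, 7066 were called in the same direction under quantile normalization, 6933 under median centring and 5959 with the mean of a gene's probe sets, where 59 were called in the opposite direction. For the named genes, 2713 values under an alternative kept direction and side of the threshold, 34 were no longer past it, 10 were newly past it and 16 changed direction; for the lists, by the direction of the test, these numbers were 597, 7, 17 and 12. HK2 changed by -0.41 with the mean of its probe sets, as its 2 dimmer probe sets fell, one from 121 to 35.7. CD163 was at -0.30 when read by another probe set, and the tricarboxylic acid list, with a median of 0.0020, passed downward in fry (adjusted p = 0.0182) where camera gave an upward direction; the cause was not tested. The other 14 and 11 values that changed direction passed in neither setting, and the cause was not tested. HIF1A was at -0.017 to 0.011 when single arrays were left out, 0.034 under quantile normalization, 0.0026 with array weights and 0.0053 without both arrays numbered 0, where ALAS2 was at 0.0030. Median centring put IRF4 at -0.0092, LDHA at -0.024 and the tricarboxylic acid median at -0.063. With the mean of a gene's probe sets COL1A1, DCN and LYZ were at 0.46, -0.082 and 0.083, and the tricarboxylic acid and apoptosis medians at 0.0020 and 0.040. Without probe sets that can bind several transcripts they were at 1.26 for COL1A1, -0.0047 for DCN and -0.00023 for the tricarboxylic acid list. Erythroid and epithelial markers turned with the replicate block and fry (median -0.080), quantile normalization (-0.082) and without 1 normoxia array. Ribosomal proteins turned under quantile normalization (-0.0064), apoptosis in fry (0.14) and the tricarboxylic acid list without 1 hypoxia array. With single arrays left out the medians of the first and last were at -0.12 to 0.010 and -0.044 to 0.029. Medians of lists, which can differ in sign from the test, changed sign in 35 values, all of lists that passed in neither setting. The autophagy list passed under 9 alternatives (adjusted p as low as 0.0307 in camera). The correlation of the deviations of same-numbered arrays from the group means, across genes, was 0.241, 0.00638 and 0.207 for the numbers 0, 1 and 2 over all genes, and 0.577, 0.191 and 0.565 over genes above the median brightness. With the replicate block 3493 genes were higher, 4140 lower and 10 lists passed, and of the named genes CD163 alone lost its call (adjusted p = 0.0505). Array control probe sets were not run, since none were among the probe sets used here, and the robust fit gave no list values, since camera has no such setting. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05: 1 split, the real one, called as many as 7403 genes in limma, and the highest of the others called 0 (8826 and at most 968 at an unadjusted p of 0.05). Over all their alternatives, adjusted p-values ran from 0.0296 to 0.274 for CD163, 0.00898 to 0.166 for CD3D, 0.000901 to 0.107 for CCND2, 1.51e-07 to 0.00306 for HK2, 0.0173 to 0.463 for EPAS1, 0.000479 to 0.0608 for CREBBP, 0.000127 to 0.502 for IDH3G, 2.72e-07 to 0.125 for MKI67 and 7.16e-07 to 0.0727 for TFRC. They ran from 1.92e-05 to 0.553 for CR2, 0.000349 to 0.182 for CD247, 3.33e-05 to 0.812 for HBB, 0.0208 to 0.562 for CLDN4 and 0.0127 to 0.359 for RPL6. For the lists they ran from 0.0182 to 0.995 for the tricarboxylic acid cycle, 0.000687 to 0.495 for autophagy, 0.000177 to 0.324 for the endoplasmic reticulum, 2.01e-10 to 0.164 for glycolysis, 7.80e-11 to 0.167 for the mitochondrial ribosome and 6.83e-06 to 0.389 for the proteasome. Dim genes limit these results: of 8205 genes with a mean intensity up to 64, 9.40% were called, against 68.0% of those between a log2 intensity of 10 and 12.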

Other observations

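In this part, the 5 gene lists, the comparison of probe sets by brightness, the tests that set the replication against the mitosis genes and the interval of the mitosis median were chosen only after the results were seen, while both of those lists and their camera tests were planned. Probe sets of metallothioneins, small metal-binding proteins, read higher in hypoxia, with 7 of 8 genes past the threshold in limma (7 and 0 adjusted over the list alone) and a median change of 2.07 (camera adjusted p over the 5 lists = 5.67e-06; adjusted p = 0.173 with an estimated correlation). MT2A went from 453 ± 20.4 to 2624 ± 131 and MT1X from 417 ± 47.5 to 1837 ± 143. The genes of this family are close in sequence, and all 7 that passed were read by probe sets marked as able to bind several transcripts, so these calls are not shown to be of separate genes. The member read otherwise, MT1M, was dim and did not pass (0.29, adjusted p = 0.206). Of 19 genes of purine and pyrimidine synthesis, 15 fell and 2 rose (2 and 16 adjusted over the list alone; median -0.62, camera adjusted p = 2.29e-06, adjusted p = 0.173 with an estimated correlation). CTPS1 fell by 2.35, PFAS by 2.26 and CAD by 2.02, while GART and IMPDH2 rose by 0.47 and 0.42. Of 15 genes of G1 control, namely cyclins, their kinases CDK2, CDK4 and CDK6, the phosphatase CDC25A and inhibitors of the kinases, 8 fell and 3 rose (3 and 8 adjusted over the list alone; median -0.20, camera adjusted p = 0.104). CDC25A fell by 2.56, CCND1 by 1.78 and CDK4 by 1.55, while the inhibitor genes CDKN1C and CDKN1B rose by 3.28 and 0.50 and CDK6 by 0.39. Histone genes of the class called replication-dependent went both ways, with 7 of 39 higher, led by H2AC6 at 3.22 and H2BC5 at 2.36, and 7 lower (7 and 7 adjusted over the list alone, camera adjusted p = 0.432). The median normoxia intensity of these histone genes was 53.6, where signal cannot be told from background. Whether their transcripts followed replication here was not tested. A mixed list of 9 genes held repressors of the BHLHE family, members of the MAX network, among them the dimerisation partner MLX, and the zinc-finger factor KLF10. Of these 5 rose, among them BHLHE41 at 2.52 and BHLHE40 at 1.92, and 4 fell, KLF10 and MLX included (5 and 4 adjusted over the list alone; camera adjusted p = 0.305).

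The brightest probe sets of glycolytic genes read smaller changes than those of the other members. The values argue only against scale differences left between the deposited arrays as the cause. Quantile normalization raised the median change of the 6 brightest members by 0.054, where a rise of 0.3 had been set as the mark of such an effect. The arrays were already alike, with medians of 54.95 to 60.1, so little could move. Median centring cannot alter the gap by construction, and the authors' own scaling was not undone, so its effect was not tested. Saturation of bright probe sets remains a candidate explanation: over genes with 2 or more probe sets, the slope of the brighter probe set's change on the dimmer one's, at a log2 intensity of at least 8, was 0.212 for 66 genes with a brighter probe set above a log2 intensity of 13, and 0.520 for 1178 genes where it lay between 10 and 12 (difference -0.31, 95% bootstrap interval -0.42 to -0.19). Among the 6, PGK1 read 0.41 at its brightest probe set and 0.51 to 1.22 at 5 dimmer ones, ENO1 0.40 against 0.55, 0.75 and, from a dim level in normoxia, 1.96, and TPI1 0.25 against 0.33 and 0.31. A smaller response of enzymes that are already abundant stays open too. The dimmer probe sets of TPI1 read little more, but they lay at 7510 in normoxia, itself bright, and at 61.7, which is dim, so they cannot decide it. LDHA and PGAM1 have 1 probe set each and the 3 of GAPDH are all bright.

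Replication genes fell, while the list of mitosis genes did not pass in camera and passed upward in fry (fry adjusted p = 0.000597). This may mean that transcription of replication and S phase genes was lowered without a matching loss of dividing cells. A settled fall in the share of cycling cells alone would lower both lists, but the median change of the mitosis genes was 0.060 (95% bootstrap interval over genes -0.046 to 0.18). Hypoxia was sampled only at 24 h. A fall in entry to the cycle too recent to have reached the mitosis genes is therefore not excluded. Quantile normalization of the deposited values left the difference of the medians at -1.68, and median centring cannot move it by construction. Neither undoes the authors' own scaling, whose effect was not tested. Among 24 replication and 30 mitosis genes with normoxia intensities of 1000 to 6000 the difference was -1.85 (95% bootstrap interval over genes -2.18 to -1.63). For these genes compression of bright signals does not account for it. Both bootstrap intervals treat genes as independent and leave out the spread between arrays. An arrest of cells in G2 or mitosis, which would keep the second list high while the first falls, and a faster loss of some transcripts were not tested, so the reading remains a hypothesis found and tested on the same arrays.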
